A study of Gallus gallus with 32 samples.

How the data were processed

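RNA from the anterior pituitary gland of chickens was measured on 32 spotted cDNA arrays. The birds came from a Fat and a Lean line, selected in opposite directions for the weight of abdominal fat, and were 1, 3, 5 or 7 weeks old. Line and age make 8 groups with 4 arrays each, and the labels call the 4 arrays of a group biological replicates. On every array the amplified RNA of a sample carried the dye Cy3, and a pool of all 32 RNAs carried Cy5, so each value is a log2 ratio of a sample over the same pool.

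The authors deposited 1 file per array, written by TIGR Spotfinder 2.2.4 per the file headers, and 1 table of the whole series. The deposited per-array files hold spot intensity and local background for both dyes, as sums over the pixels of a spot, with no normalization. They also hold other measures of each spot per the file headers, namely its area and saturation, and Spotfinder's quality score and quality marks. The deposited table holds log2 ratios of sample over pool, normalized by the authors in a way not given in the sources used here. The per-array files were the source of every value below, and the table served as an alternative. For each array, the log2 ratios normalized here correlated across probes with those of the table at 0.39 to 0.65, with a median of 0.61. For 31 of the 32 arrays the table's column fitted that array's own file best.

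Each file held 19200 spots in 48 grid blocks of 20 rows and 20 columns. Spots with a bad quality mark in either dye were left out, which left 14008 to 16134 usable spots per array. The median Cy3 signal was 3.73 to 8.92 times its local background and the median Cy5 signal 8.76 to 18.4 times. Between 15 and 91 spots per array were saturated. The number of arrays limits the precision.

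Intensities were divided by spot area and corrected for background with the normexp model (offset 50), then the log2 ratios were normalized within each array by a loess curve over intensity. No normalization between arrays was used. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with matplotlib 3.10.9 for the plots. A probe was tested when it was usable on at least 24 arrays and on at least 2 arrays of every group. This kept 14745 probes, 8873 of them with a gene, for 5763 genes. Gene symbols came from the platform's probe table and a RefSeq gene table, and the other 5872 tested probes carry none. No genome positions are given, since no build was stated for the probes.

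Every comparison came from 1 limma model with a mean for each of the 8 groups and 24 residual degrees of freedom, so the spread is shared by all groups. Tests were limma's moderated tests, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The line difference is fat minus lean, as a mean over the 4 ages with equal weights and at each age. The age changes are means of both lines, step by step and from week 1 to week 7. A moderated F test asked whether any age differed from week 1, and another whether the line difference depended on age. Changes were also added to simulated arrays, drawn independently with each probe's residual spread and missing values. There 91% of probes with a line difference of 0.5 (log2) over all ages were called, against 36% at week 7 alone. For the change from week 1 to week 7 the share was 61% at 0.5 and 95% at 1. Of the calls in these simulations, 4.07% to 5.47% were false. The simulated arrays had equal spread, no correlation with each other and no shared scan, so these shares may not hold for the real arrays.

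Before the data were examined, 29 lists of genes and of cell type markers were fixed, 28 of which had at least 4 measured genes and were tested. A list's shift was tested with limma's camera at a preset correlation of 0.01, with the brightest probe standing for each gene and members matched through current and older symbols, and again with an estimated correlation and with fry. The named genes follow a rule fixed at the same time. It takes up to 10 genes in each direction with the largest line difference past the threshold and 1 sign at all 4 ages, and the 10 largest rises and falls from week 1 to week 7 with 1 sign in both lines. It further takes the 3 largest per direction for each age step, the 3 smallest p values of the interaction, every measured hormone, and up to 4 examples per list, not all of which are given. Each gene stands for its brightest probe. The other genes named below were chosen after their values were seen.

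The week 7 replicate 2 files of the lean and the fat line hold 1 and the same scan. Of the spots, 54.4% had the same area and quality score in both files, against at most 1.98% in any other pair of arrays, and the normalized ratios correlated across probes at 0.995. The fat file held intensities from which the background had already been taken off, and it was added back. Which line the scan belongs to was not settled, and both files stay in the model as its design had been fixed. The model thus counts 1 scan as 2 of its 32 arrays, and the SEs of age changes that include week 7 may be too small. Counts without both files are given as an alternative chosen after the data were examined.

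On the array of fat week 7 replicate 4 the log2 ratio sloped across the slide. Its grid block medians spanned 2.07 on the log2 scale, against 0.14 to 0.78 on the other 31 arrays. A loess per grid block (span 0.4) was among the alternatives fixed beforehand and removes such a slope. The file headers give 9 different days, 6 of which hold both lines at 1 age, and no day holds week 1 together with week 7.

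Fixed alternatives were other normalizations within and between arrays, no background correction, the deposited table, other filters, the replicate number or the header day as a block, other moderation, array weights, and each array or replicate number left out in turn. The models without the shared scan, with plain background subtraction, with replicate block and no shared scan, and with block loess without the scan and the sloping array were added after the data were examined. For splits, the line labels were shuffled within each age and the age labels within each line, with 100 splits each, and all 35 splits of the 8 arrays of each age were made. Groups of 4 arrays were searched for values far from the rest with Dixon's test (limit 0.829).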

Results

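The anterior pituitary releases the hormones that govern growth, metabolism, stress and reproduction. Its RNA was profiled in chickens of a Fat and a Lean line, selected for high or low abdominal fat, at 1, 3, 5 and 7 weeks of age. Each of the 8 groups of line and age had 4 arrays, 32 in all, and every array compared a sample with a common pool. Between 14008 and 16134 spots per array were usable, with a median of 15420, and 14745 probes were tested. The lean and the fat array of week 7 replicate 2 hold the same scan, so that at most 1 of them can show its own line. Age changes that include week 7 count this scan as 2 arrays.

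The first comparison asked which transcripts differ between the Fat and the Lean line whatever the age. SUFU, a repressor of Hedgehog signalling, was lower in fat birds by the largest margin, with a log2 difference of -0.92 (SE 0.13, 32 arrays, 1.90-fold, adjusted p = 0.000485). CD69L, named for its likeness to a receptor of activated lymphocytes, differed by -0.91 (SE 0.13, adjusted p = 0.000442), and CAD, the enzyme that starts pyrimidine synthesis, by -0.63 (SE 0.10, adjusted p = 0.00209). Each of these 3 was higher in the lean array in 15 of 15 comparisons of arrays with the same age and number. CPQ, a secreted carboxypeptidase, was higher in fat birds by 0.62 (SE 0.12, 1.54-fold, adjusted p = 0.00852) and higher in the fat array in 12 of the 15. A second CPQ probe also passed, at 0.61, whereas the other 3 probes of CAD, none past the threshold, differed by -0.17 to 0.08.

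The other genes past the threshold with 1 sign at all 4 ages differed by less. TSPAN7, a membrane tetraspanin, was lower in fat birds by -0.47, LGI1, a secreted neuronal protein, by -0.36, and EXOG, a mitochondrial nuclease, by -0.36, with a second EXOG probe at 0.18 that did not pass. The RNA-binding protein STAU2 was lower by -0.61 (adjusted p = 0.0412), and with a loess per grid block its adjusted p was 0.136, with the call lost in 32 of 54 settings. LGI1 had an adjusted p of 0.0528 with that loess, and with the header day as a block STAU2 had 0.0691 and LGI1 0.0974. RNF126, a ubiquitin ligase, was higher in fat birds by 0.36 and SLC35B3, a transporter of the Golgi, by 0.30. In all, limma called 38 of 14745 probes, 15 higher and 23 lower in fat birds, and 20 of the 38 carry no gene symbol.

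The call count depended on the arrays at week 7, on which replicates were used and on the processing. It was 101 without the shared scan, and all 38 were among them. It was 131 without lean week 7 replicate 2 alone, 41 with the header day as a block, and 10, 8 and 11 without replicates 1, 3 and 4. It was 295 with array weights, 78 with the replicate number as a block, 21 with spots of poor quality marks kept, 9 with 1 probe per gene and 7 in the authors' table. Within the 6 header days that hold both lines at an age, 38, 38, 36, 31, 38 and 36 of the 38 probes had the same sign as over all arrays, which include those of the day.

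**Figure D1:**
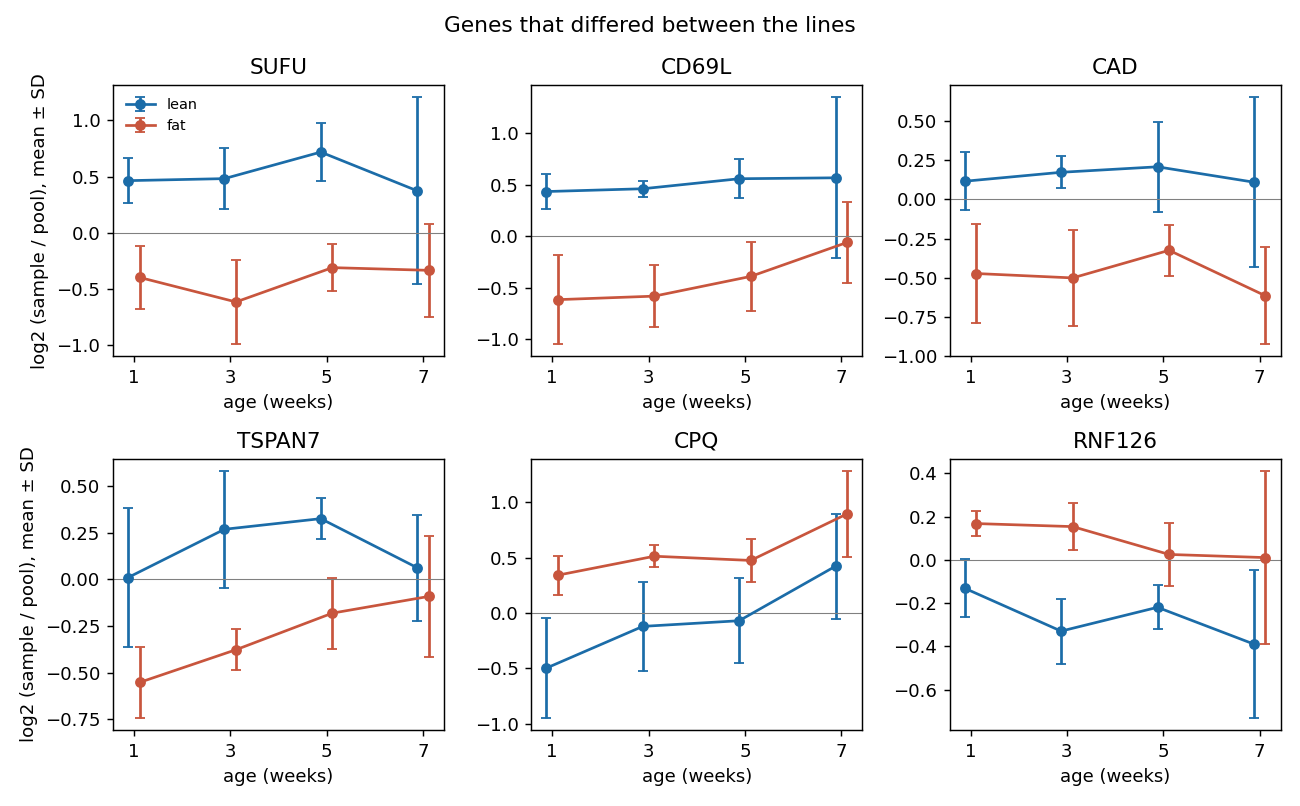
Mean log2 ratio of sample over pool (points) with the SD of 4 arrays (bars) against age in weeks, for 6 genes with a line difference, lean in blue and fat in red. SUFU, CD69L, CAD and TSPAN7 were higher in lean birds and CPQ and RNF126 in fat birds at each of the 4 ages.

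None of the 6 hormone transcripts measured passed the test between the lines. The largest difference over ages was that of TSHB, the beta chain of thyrotropin, at -0.38 (SE 0.17, adjusted p = 0.429). FSHB, the beta chain of follitropin, differed by 0.19 (SE 0.25), POMC, the precursor of corticotropin, by 0.11 (SE 0.07), GH by -0.09 (SE 0.17), PRL by -0.08 (SE 0.12) and CGA, the shared alpha chain, by -0.02 (SE 0.15). At week 7 FSHB was 1.28 higher in fat birds (SE 0.50, unadjusted p = 0.0166, adjusted p = 0.387). Without the shared scan the FSHB difference was 1.70 (adjusted p = 0.124), and with a loess per grid block and neither that scan nor fat week 7 replicate 4 it was 2.05 (adjusted p = 0.247). It passed only with the replicate number as a block and no shared scan (1.70, adjusted p = 0.0392), a setting chosen after the data were seen.

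**Figure D2:**
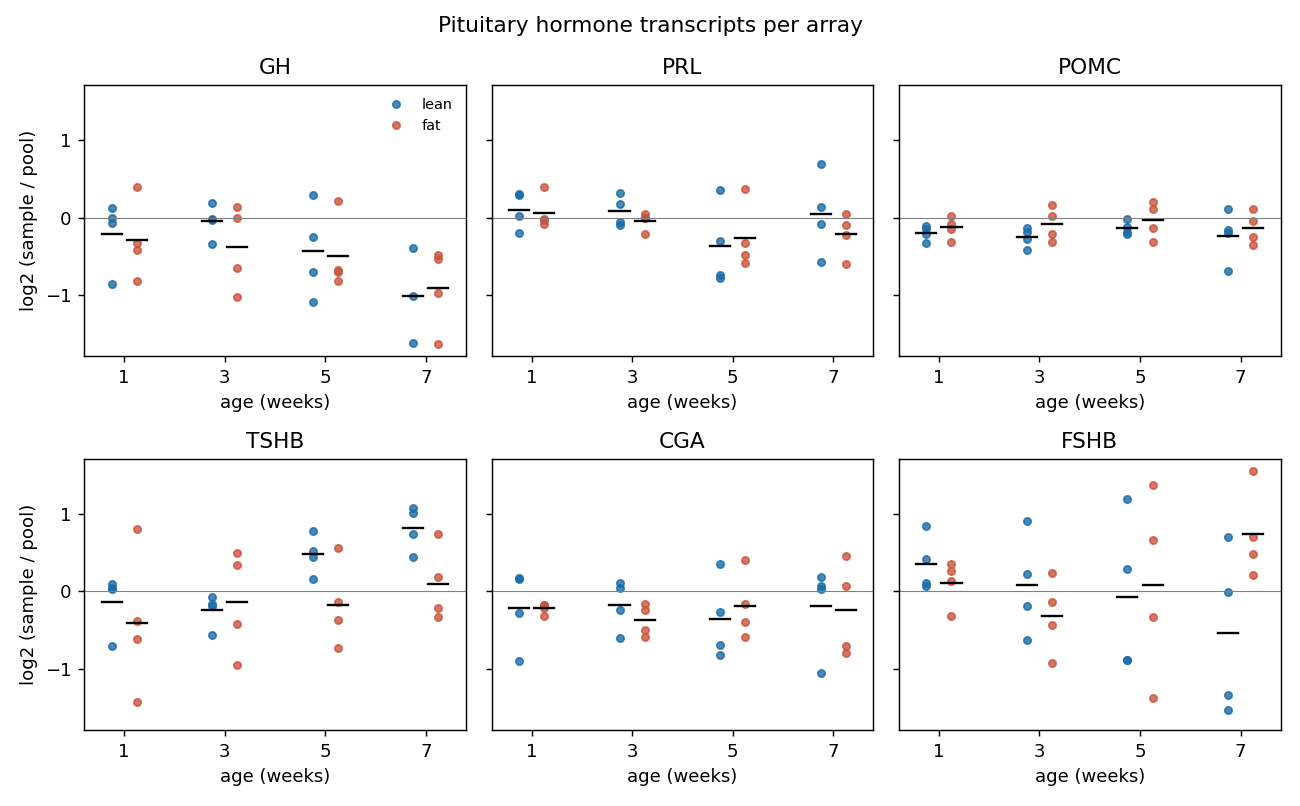
Log2 ratio of sample over pool for 6 hormone transcripts on each array (points) with group means (black lines) against age in weeks, lean in blue and fat in red. At week 7 the 8 points of FSHB ranged from -1.53 to 1.55.

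Among the 28 tested lists, markers of lymphocytes and macrophages were shifted towards higher values in fat birds, with a median of 0.12 and 12 of 14 genes higher (camera, adjusted p = 0.0249, and 0.531 with an estimated correlation). No other list passed. Among those higher in fat birds were muscle, cartilage and bone, with 14 of 15 higher and a median of 0.09 (adjusted p = 0.0656, though past the threshold in 19 settings). Interferon and antigen presentation, with 14 of 16 higher and a median of 0.06 (adjusted p = 0.111, past the threshold in 5 settings), was another. So were fibroblasts and extracellular matrix, with 22 of 32 higher (adjusted p = 0.192). Among those lower were oxidative phosphorylation, with 26 of 40 lower and a median of -0.05 (adjusted p = 0.0656, past the threshold in 12 settings), and ribosomal proteins, with 30 of 45 lower (adjusted p = 0.111, past the threshold in 9 settings). No gene of the lymphocyte and macrophage list passed over all probes, and 4 passed when adjusted over the list alone, all upward. These were CTSS, a lysosomal protease, at 0.22, C1QC, a complement chain, at 0.25, IL2RG, a cytokine receptor chain, at 0.21, and JCHAIN, the joining chain of antibodies, at 0.37. Over all alternatives the list's adjusted p ranged from 0.000305 to 0.531. The call was lost in 11 of 57 settings, among them fry (adjusted p = 0.176). It was lost as well without lean week 1 replicate 2 (adjusted p = 0.0594), lean week 3 replicate 1 (0.0535), lean week 5 replicate 2 (0.0504), fat week 7 replicate 1 (0.0827) or fat week 7 replicate 2 (0.0714). With the header day as a block the adjusted p was 0.0453, and within the 6 days the medians were 0.10, 0.10, 0.13, 0.08, -0.02 and 0.05. The other 27 lists had adjusted p values from 0.0656 to 0.998. The count of 1 shifted list became 0 without any of the 5 arrays just named. It became 2 without lean week 1 replicate 3, fat week 1 replicate 3, lean week 3 replicate 4, lean week 7 replicate 3 or fat week 7 replicate 4, and 3 without lean week 5 replicate 1, lean week 7 replicate 2 or fat week 7 replicate 3. It became 4 without fat week 1 replicate 4, lean week 3 replicate 2, or fat week 3 replicate 3, and 4 without fat week 5 replicate 3 or replicate 4. With all arrays of replicate number 1, 2, 3 or 4 left out in turn, it was 0, 0, 5 and 4.

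The line difference was then tested at each age. No probe passed in limma at any age, while 525 probes at week 1, 421 at week 3, 533 at week 5 and 1799 at week 7 had an unadjusted p under 0.05. By chance a share of 0.05 of the 14745 tested probes would have such a p. In this model, whose spread is shared by all groups, the counts at weeks 1, 3 and 5 lay below that. With only the groups compared these counts were 670, 840 and 578, and with array weights 867, 962 and 854. Whether they lay below that share thus depended on the model. The count at week 7 depended on the processing and on single arrays. At an unadjusted p under 0.05 it was 437 with scaling between arrays, 319 in the authors' table and 336 with only the groups compared, in each case the lowest of the 4 ages. Without the shared scan 3 probes passed and 3108 had an unadjusted p under 0.05. Without lean week 7 replicate 2 alone 96 passed, and without fat week 7 replicate 2 alone 1 passed. With the replicate number as a block no probe passed and 2780 had an unadjusted p under 0.05, and with that block and no shared scan, a setting chosen after the data were seen, 746 passed and 3986 did. Without lean week 7 replicate 3 no probe passed and 525 had an unadjusted p under 0.05, and without fat week 7 replicate 4 these were 0 and 937. At week 1, 1 probe passed without lean replicate 2 and 1 without fat replicate 4, and at week 5, 5 passed without fat replicate 4.

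Whether the line difference depended on age was tested as an interaction. No probe passed in limma, and 284 had an unadjusted p under 0.05, fewer than a share of 0.05 of the 14745 tested. However, 1 probe passed without lean week 1 replicate 2 and 2 without fat week 5 replicate 4. In limma the smallest unadjusted p values among genes were 0.00201 for KATNAL1, 0.00301 for FIBIN and 0.00586 for CDK2AP1, each with an adjusted p of 1. Of the hormones, FSHB had the smallest interaction p, at 0.101 before adjustment.

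The age comparison asked how the gland's transcripts change as the birds grow. From week 1 to week 7, as the mean of both lines, 2 globins and 11 of 28 cell cycle genes passed downward and 5 of 10 genes of prohormone processing and granule cargo upward. HBBA, a beta globin, fell by 1.87 (SE 0.15, 3.65-fold, adjusted p = 3.54e-09) and HBA1, an alpha globin, was 2.82-fold lower (adjusted p = 2.32e-08). In lean birds the mean log2 ratio of HBBA went from 1.08 ± 0.31 (SD, n = 4) at week 1 to -0.51 ± 0.21 at week 7, and in fat birds from 1.35 ± 0.29 to -0.79 ± 0.52. Limma called 1317 probes, 781 higher and 536 lower at week 7, and the F test over the 4 ages called 578.

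Of the 28 measured cell cycle genes, 24 were lower at week 7, and 11 passed downward and 1 upward (15 and 1 adjusted over the list alone). RRM2, a subunit of ribonucleotide reductase, fell by 1.67, CCNB1, a mitotic cyclin, by 1.55 (SE 0.13, adjusted p = 5.16e-09), TOP2A, the topoisomerase of dividing cells, by 1.37, and STMN1, a regulator of microtubules, by 0.80. The replication protein PCNA was the member that rose, by 0.34 at its brightest probe (adjusted p = 0.0276), while a second PCNA probe fell by 0.40 (adjusted p = 0.0188). The median of the list was -0.33 (camera, adjusted p = 2.64e-09), and the call held with an estimated correlation (adjusted p = 0.000329). Of the genes with the largest falls outside the list, the mitotic kinase PBK fell by 1.53 and the spindle protein KNSTRN by 1.66, or by 1.09 without lean week 1 replicate 1 (adjusted p = 2.4e-08). GPM6B, a membrane proteolipid of neural cells, fell by 1.55. LY6E, a surface protein, fell by 1.22, or by 0.64 with a loess per grid block and neither the shared scan nor fat week 7 replicate 4 (adjusted p = 0.178), and its other probes were at -0.78 and 0.00414. The interferon-induced gene OASL fell by 1.46, or by 1.18 in that same setting (adjusted p = 0.0527).

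Of 10 genes of prohormone processing and granule cargo, 8 were higher at week 7 and 5 passed, all upward (also 5 adjusted over the list alone). SCG3, a granin that sorts granule content, rose by 1.19 (SE 0.17, adjusted p = 1.4e-05) at a probe that varied together with probes of unrelated genes, PCSK1, a convertase that cuts prohormones, by 1.12, CHGB, a granin, by 0.99, SCG5, a chaperone of a convertase, by 0.58, and CPE, the carboxypeptidase that trims prohormones, by 0.42. The median was 0.31 (camera, adjusted p = 0.000165, and 0.000134 with an estimated correlation), and that of the 9 genes other than SCG3 was 0.21. The 8 measured red blood cell markers had a median of -0.27, with 7 lower, of which the 2 globins passed, and 4 passed downward adjusted over the list alone (adjusted p = 0.00027, and 0.0201 with an estimated correlation). Muscle, cartilage and bone markers had a median of -0.18 with 13 of 15 lower, and the cartilage collagen COL2A1, at -0.72, was the only member that passed over all probes, with 2 downward adjusted over the list alone. That list's call (adjusted p = 0.0355) was lost in 15 of 58 settings, among them an estimated correlation (adjusted p = 0.864) and fry (adjusted p = 0.107). The list also lost its call without lean week 1 replicate 2 (0.0579), fat week 1 replicate 1 (0.0543), fat week 1 replicate 2 (0.0756), lean week 7 replicate 3 (0.223) or fat week 7 replicate 3 (0.116). Over all alternatives its adjusted p ranged from 0.00287 to 0.864, while those of the other 3 lists stayed at 0.0201 or below. The other 24 lists had adjusted p values from 0.0519 to 0.9.

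**Figure D3:**
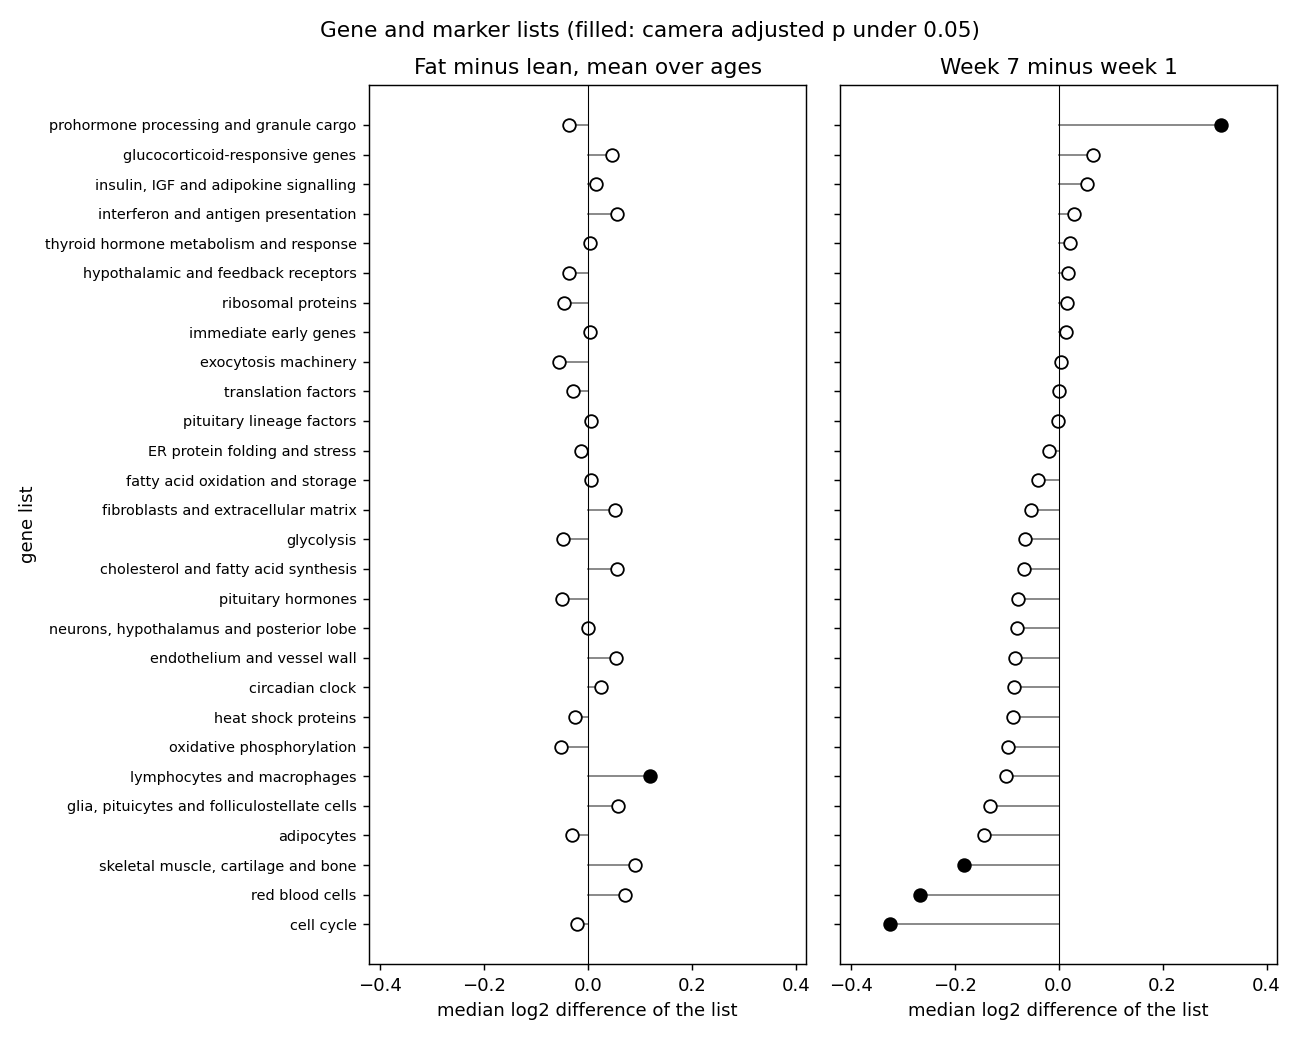
Median log2 difference of the measured genes of each list, for fat minus lean over all ages (left) and for week 7 minus week 1 (right). Filled points passed camera at a preset correlation, namely 1 of 28 lists for the line and 4 of 28 for age.

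The largest rises from week 1 to week 7 included genes of several kinds. ADCY2, an adenylyl cyclase, rose by 3.00 (SE 0.50, 7.98-fold, adjusted p = 0.000169), MMP15, a membrane-bound matrix protease, by 1.31, and GPC3, a glypican of the cell surface, by 1.29. The probes of ADCY2 and MMP15 correlated at 0.915 among arrays, and a second probe of MMP15 was at -0.01. IGFBP7, a secreted binding protein, rose by 1.33, KLHL14 by 1.28, INTS8, a subunit of the Integrator complex, by 1.28, OGN, a matrix proteoglycan, by 1.27, TM2D2 by 1.23, ATXN7L1 by 1.22 and H2AFY, the macroH2A histone, by 1.21. The probes of KLHL14, INTS8, ATXN7L1, H2AFY, OGN and IGFBP7 also varied together among arrays of a group, with correlations from 0.81 to 0.975. A second probe of INTS8 showed no rise, at -0.03 (adjusted p = 0.804), and a second probe of OGN rose by 1.01.

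Single members of further lists passed from week 1 to week 7 without a shift of the list. Among those upward were BTG2, an antiproliferative early gene, at 1.09, FABP5, a fatty acid binding protein, at 1.03, SOX10, a glial transcription factor, at 1.20, ADIPOR1, an adiponectin receptor, at 0.79, EIF2S1, a translation factor, at 0.81, SDHD, a subunit of succinate dehydrogenase, at 0.72, and the clock gene HLF at 0.44. Second probes did not pass for SOX10 (-0.40), EIF2S1 (-0.03), BTG2 (0.18) and HLF (0.29), nor did the other probes of SDHD (-0.12 and -0.00394). Among those downward were MGP, the matrix Gla protein, at -1.15, PGK2, a phosphoglycerate kinase, at -0.58, and GATA2, a factor of the gonadotrope and thyrotrope lineage, at -0.39, with an adjusted p of 0.124 for GATA2 with a loess per grid block. The call of GATA2 was lost in 29 of 55 settings, and its second probe was at 0.30 (adjusted p = 0.315). Of the hormones none passed, with TSHB at 0.73 (SE 0.24, adjusted p = 0.0547, and 0.0418 with a loess per grid block) and GH at -0.71 (SE 0.24, adjusted p = 0.0615). TSHB passed in 12 settings, among them leaving out fat week 1 replicate 4 (0.93, adjusted p = 0.00719), and had 0.35 with the header day as a block (adjusted p = 0.814). GH passed in 6 settings, among them the replicate number as a block (adjusted p = 0.00687). Without the shared scan GH was at -0.43 (adjusted p = 0.22), with a loess per grid block and without fat week 7 replicate 4 as well at -0.37 (adjusted p = 0.409), and its second probe was at 0.14 (adjusted p = 0.464).

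The named genes past the threshold kept their signs, though the largest rises and falls had been chosen for 1 sign in both lines. The count of 1317 depended on the processing. It was 2354 without the shared scan, 834 with a loess per grid block, of which 642 were among the 1317, and 843 without fat week 7 replicate 4, whose ratios slope across the slide. It was 850 without lean week 1 replicate 3 and 796 without fat week 1 replicate 2. Lower still were 561, 610 and 605 without replicates 1, 3 and 4, 611 in the authors' table and 544 with only the groups compared. With the header day as a block no probe passed in limma, so that each gene named above lost its call, 1411 had an unadjusted p under 0.05, and the F test called 13. No day held both week 1 and week 7, so that this blocked change rests on days that share other ages, and no value within a day can be given. With the day as a block the lists had medians of -0.21 for the cell cycle (adjusted p = 0.00335), 0.33 for granule cargo (0.013), -0.16 for red blood cells (0.013) and -0.20 for muscle, cartilage and bone (0.0397), and no member passed.

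**Figure D4:**
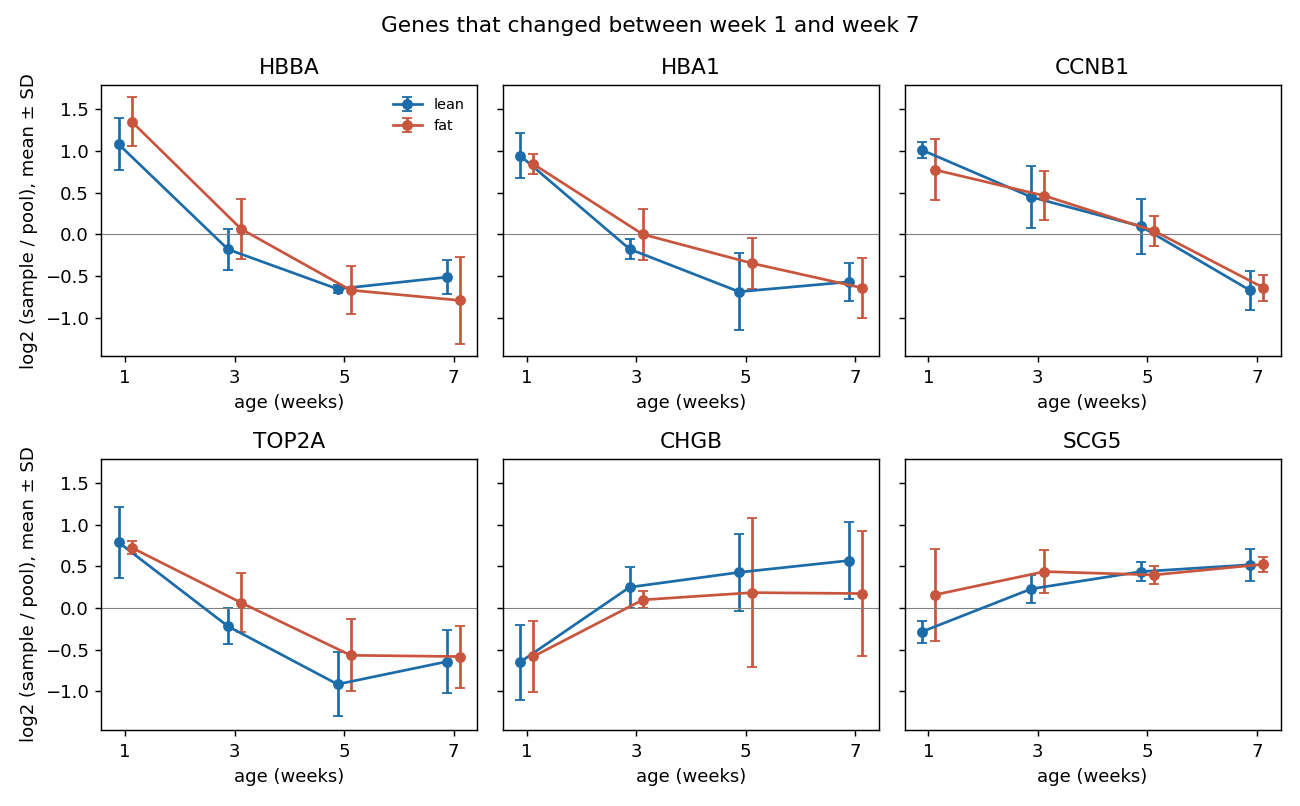
Mean log2 ratio of sample over pool (points) with the SD of 4 arrays (bars) against age in weeks for 6 genes, lean in blue and fat in red. HBBA, HBA1, CCNB1 and TOP2A were lower at week 7 than at week 1 in both lines, and CHGB and SCG5 were higher.

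The step from week 1 to week 3 held the larger part of the globin change. HBBA fell by 1.28 (SE 0.15, adjusted p = 2.4e-05), HBA1 by 0.98 and TOP2A by 0.83, while ADCY2 rose by 3.03, MMP15 by 1.42 and LOC420294 by 0.88 (adjusted p = 0.0448, and 0.0579 with a loess per grid block). With the header day as a block the adjusted p was 0.121 for LOC420294 and 0.0559 for TOP2A. Limma called 49 probes, 32 higher and 17 lower at week 3. The count was 75 without the shared scan and 26 with the header day as a block. It was 32 without lean week 1 replicate 3, 27 without fat week 1 replicate 3, 26, 25 and 26 without lean week 3 replicates 2, 3 and 4, and 28, 29 and 28 without fat week 3 replicates 1, 3 and 4. On the 2 days that hold week 1 and week 3 in both lines, all 49 probes had the sign seen over all arrays, which include those of the day. On these days the cell cycle list had medians of -0.02 and -0.12, the red blood cell list -0.28 and -0.09, the granule list 0.27 and 0.07, and the muscle, cartilage and bone list -0.19 and 0.07.

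From week 3 to week 5 OASL fell by 1.62 (SE 0.31, adjusted p = 0.0261) and GPM6B by 1.32 (SE 0.23, adjusted p = 0.0185). Limma called 8 probes, all lower, and none with the header day as a block, where 348 had an unadjusted p under 0.05. On the 3 days that hold both ages 8, 8 and 7 of the 8 had the sign seen over all arrays, which include those of the day. The cell cycle list had medians of -0.08, -0.09 and 0.06 on these days, and the red blood cell list -0.12, -0.11 and -0.02. The granule list had 0.06, 0.14 and 0.02, and the muscle, cartilage and bone list -0.08, -0.03 and 0.10. The count was 2 without lean week 3 replicate 1, 2 or 4, fat week 3 replicate 1 or 3, lean week 5 replicate 2 or fat week 5 replicate 3. It was 3 without fat week 3 replicate 4, lean week 5 replicate 3 or fat week 5 replicate 2.

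From week 5 to week 7 no probe passed in limma and 1175 had an unadjusted p under 0.05. GH differed by -0.49 (SE 0.24, unadjusted p = 0.0507) and TSHB by 0.30 (SE 0.24, unadjusted p = 0.218). Leaving out 1 array gave 0 to 4 called probes, namely 4 without fat week 7 replicate 1, 2 without fat week 1 replicate 4, lean week 5 replicate 2, fat week 5 replicate 4 or lean week 7 replicate 1, 1 without fat week 1 replicate 3, lean week 3 replicate 2, fat week 3 replicate 3 or lean week 5 replicate 4, and 0 without any other. On the 2 days that hold both ages, the cell cycle list had medians of -0.07 and -0.01 and the red blood cell list 0.14 and -0.09. The granule list had 0.06 and 0.19, and the muscle, cartilage and bone list 0.06 and -0.14.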

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

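The loess per grid block, the header day as a block and leaving out single arrays were settings fixed before the data were examined, and their use as tests here was chosen later. The bounds for header day for the co-varying probes, the widely spread array at week 7 and blood for the cell cycle genes were written before these values were read, though the array's count had been computed and 2 rules were changed afterwards, as stated below. All other bounds and tests, the splits included, were chosen after the values were seen.

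Of 111 searches, each of 1 measure or hormone in 1 group of 4 arrays, 8 found a value far from the other 3. Chance singles out about 1 in 20, or 5.55 of 111, and as the searches share the same 8 groups they are not independent. Lean week 3 replicate 4 had 14790 usable spots against 15580 to 15590. The correlation, across probes, with the mean of the other arrays of the group was 0.272 for lean week 7 replicate 2 against 0.635 to 0.703, and 0.661 for fat week 1 replicate 3 against 0.571 to 0.573. Lean week 7 replicate 2 is a copy of the shared scan, and the fat copy was at 0.418 against 0.492 to 0.574. Without the lean copy alone 96 probes passed between the lines at week 7, and without the fat copy alone 1, which does not settle the scan's line. The grid block medians of fat week 7 replicate 4 spanned 2.07 (log2) against 0.25 to 0.37. CGA had a log2 ratio of -1.06 in lean week 7 replicate 4 against 0.03 to 0.19, and GH 0.22 in fat week 5 replicate 1 against -0.82 to -0.67. PRL was at 0.39 in fat week 1 replicate 4 against -0.08 to -0.01, and TSHB at -0.70 in lean week 1 replicate 2 against 0.03 to 0.10. For the line by age interaction limma called 0 probes, with 284 at an unadjusted p under 0.05.

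Among the rises from week 1 to week 7, probes of unrelated genes, SCG3, OGN and H2AFY among them, varied together among arrays. At correlations over 0.7, 0.8 and 0.9 with H2AFY there were 50, 30 and 16 of them, and over 0.8 with ATXN7L1 there were 40. The limit of 0.8 with H2AFY was chosen after the data were seen, and its 30 probes had a median rise of 1.13. A block of the slide as the whole cause is argued against, as the median was 1.11 with a loess per grid block. That loess, though, does not correct for the place within a block. Of these probes 100% lay in rows 1 to 6 of their block, against 35.5% of all tested probes. Row 6 is the highest row in which any of these 30 probes lay, so that the 100% follows from this limit. A sequence shared by many probes may be the cause, since the 14 other probes of the same genes had a median of 0.0315, but 5 of these passed upward, and it stays open. The header day stays open, with medians from week 1 to week 3 of -0.024 and 0.61 within a day against 0.37 over all arrays. Its bound first read the lowest day alone, which would have counted for the day, and was changed after the values were seen, because the days disagree; age is untested beside these.

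At week 7, 1799 probes differed between the lines at an unadjusted p under 0.05, against 421 to 533 at the other ages, but with scaling between arrays (437), the authors' table (319) or only the groups compared (336) week 7 had the fewest of the 4 ages. The shared scan stays open, as its test is void: a scan filed under both lines brings a difference near 0, so that leaving it out (3108) could hardly lower the count. The widely spread array of lean week 7 replicate 3 is a candidate explanation, as without it the count was 525, below the 643 seen at another age in that fit. The sloping array of fat week 7 replicate 4 stays open, with 937 without it against 613 at most at the other ages. Biology of line and age stays open, untested.

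Cell cycle genes had a median change of -0.325 over 28 genes from week 1 to week 7. The grid block as the whole cause is argued against, with a median of -0.32 under a loess per block (SE of the median 0.0928). The header day stays open, as the median was -0.21 with the day as a block (SE 0.0696) and -0.0177 and -0.124 from week 1 to week 3 within a day. Less blood in the older glands may account for a part and stays open, since with haemoglobin, which changed by -1.68, in the model the median was -0.22 (SE 0.0904) with 17 of 28 genes below 0. Age itself stays open, untested, and the rule that a bound must be passed by more than the SE of the median was set after the values were seen.

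Within the limits given below, the splits argue against chance for the line difference over ages. There 1 of 100 splits, the real one, called 38 probes and the highest other called 2. They do likewise, at 1 of 100 splits each, the least possible, for the age effect (578, highest other 4), the change from week 1 to week 3 (49, highest other 12), from week 3 to week 5 (8, highest other 2) and from week 1 to week 7 (1317, highest other 62). The 100 splits took no account of the replicate number or the header day, and the day is tied to age. They thus cannot tell age from header day, and with the day as a block these age counts were 13, 26, 0 and 0. The 100 splits also shuffled both copies of the shared scan as if they were separate arrays. The real labels put the copies in opposite lines and both at week 7. Shuffled line labels could put both in the same line, and shuffled age labels could put them at different ages. How far this difference between real and shuffled splits moved the counts was not tested. Chance cannot be excluded for the probes at an unadjusted p under 0.05 at single ages. As many as the real 525, 421, 533 and 1799 at weeks 1, 3, 5 and 7 came from 13, 5, 17 and 13 of 35 splits. The highest others were 1197, 844, 1640 and 5093. These splits took no account of the replicate number or, at week 7, of the shared scan. Nor can chance be excluded for the interaction (284, 90 of 100 splits, highest other 3697) or the change from week 5 to week 7 (1175, 17 of 100, highest other 3092). Why some splits gave several times the real count was not tested. For the number of shifted lists chance cannot be excluded either, neither for the line (1 list, 59 of 100 splits, highest other 4) nor for week 1 to week 7 (4 lists, 10 of 100, highest other 5). With the replicate number as a block, which these splits did not use, 3 lists were shifted by line. For single lists the splits were counted by the unadjusted camera p, with no correction for the 28 lists, so that no list is set apart from chance by them. From week 1 to week 7 they were 1 of 100 for red blood cells (2.89e-05, smallest other 0.000183), 2 for the cell cycle (9.41e-11, smallest other 2.77e-11), 2 for granule cargo (1.18e-05, smallest other 1.07e-05) and 20 for muscle, cartilage and bone (0.00507, smallest other 0.000171). Between the lines they were 6 of 100 for lymphocytes and macrophages (0.000889, smallest other 9.48e-05).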

How the results depend on the processing

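The settings without the shared scan, with replicate block and no shared scan, with a loess per grid block and neither that scan nor the sloping array, and with plain background subtraction were chosen after the data were seen. Over at most 55 settings for genes and 58 for lists and counts, no gene or list past the threshold in either setting turned direction, while some that did not pass did, as FSHB from week 1 to week 7 at -0.14 and, with the header day as a block, 0.59. Of 4415 values of named genes 3752 kept their side of the threshold and 663 no longer passed, of 3601 hormone values 21 newly passed, and of 3214 list values 26 no longer and 70 newly passed. Where no cause follows from fewer probes or arrays, the cause was not tested. Signal over background limits dim probes, with median Cy3 at 3.73 to 8.92 times background.

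Counts that moved by over 1.5 times, from 38 for the line difference over ages, 0 for the line difference at week 1, 0 for the line difference at week 3, 0 for the line difference at week 5, 0 for the line difference at week 7, 578 for the age effect, 49 for the change from week 1 to week 3, 8 for the change from week 3 to week 5, 0 for the change from week 5 to week 7, 1317 for the change from week 1 to week 7, 0 for the interaction, 1 for lists shifted by line and 4 for lists shifted by age, were as follows. A loess per grid block gave 834 for the change from week 1 to week 7. Scaling between arrays gave 1 for the line difference at week 5, 78 for the change from week 1 to week 3, 0 for the change from week 3 to week 5 (586 at an unadjusted p under 0.05) and 4 for lists shifted by line. No background correction gave 0 for lists shifted by line. Spots with poor quality marks kept gave 21 for the line difference over ages, 29 for the change from week 1 to week 3, 3 for the change from week 3 to week 5 and 2 for lists shifted by line. The authors' table gave 7 for the line difference over ages, 31 for the change from week 1 to week 3, 0 for the change from week 3 to week 5 (375 at an unadjusted p under 0.05) and 611 for the change from week 1 to week 7. Probes usable on all arrays gave 3 for the change from week 5 to week 7 and 2 for lists shifted by line. No minimum of usable arrays gave 1 for the line difference at week 1 and 1 for the interaction. The dimmest probes left out gave 3 for the change from week 5 to week 7 and 0 for lists shifted by line. The replicate number as a block gave 78 for the line difference over ages, 887 for the age effect, 1 for the change from week 5 to week 7, 2079 for the change from week 1 to week 7 and 3 for lists shifted by line. The header day as a block gave 13 for the age effect, 26 for the change from week 1 to week 3, 0 for the change from week 3 to week 5 (348 at an unadjusted p under 0.05) and 0 for the change from week 1 to week 7 (1411 at an unadjusted p under 0.05). Trend and robust moderation gave 4 for the change from week 3 to week 5 and 3 for the change from week 5 to week 7. Array weights gave 295 for the line difference over ages, 8 for the line difference at week 3, 3 for the line difference at week 7, 929 for the age effect, 191 for the change from week 1 to week 3, 13 for the change from week 3 to week 5 and 2 for lists shifted by line. Only the groups compared gave 93 for the change from week 1 to week 3, 0 for the change from week 3 to week 5 (588 at an unadjusted p under 0.05) and 544 for the change from week 1 to week 7. The shared scan left out gave 101 for the line difference over ages, 3 for the line difference at week 7, 75 for the change from week 1 to week 3, 2354 for the change from week 1 to week 7 and 3 for lists shifted by line. The replicate block and no shared scan gave 298 for the line difference over ages, 746 for the line difference at week 7, 929 for the age effect, 97 for the change from week 1 to week 3, 2570 for the change from week 1 to week 7 and 5 for lists shifted by line. A loess per grid block and neither the scan nor the sloping array gave 66 for the line difference over ages, 82 for the change from week 1 to week 3 and 774 for the change from week 1 to week 7. An estimated correlation gave 0 for lists shifted by line. Fry gave 0 for lists shifted by line. 1 probe per gene gave 9 for the line difference over ages, 251 for the age effect, 17 for the change from week 1 to week 3, 2 for the change from week 3 to week 5, 2 for the change from week 5 to week 7 and 607 for the change from week 1 to week 7.

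Leaving out each array, or each replicate number, gave counts from 8 to 131 for the line difference over ages, 0 to 2 for the line difference at week 1, 0 to 0 for the line difference at week 3, 0 to 5 for the line difference at week 5, 0 to 96 for the line difference at week 7, 242 to 629 for the age effect, 8 to 58 for the change from week 1 to week 3, 0 to 11 for the change from week 3 to week 5, 0 to 4 for the change from week 5 to week 7, 561 to 1656 for the change from week 1 to week 7, 0 to 2 for the interaction, 0 to 5 for lists shifted by line and 3 to 5 for lists shifted by age. Deviations of arrays from their group means correlated across probes at a mean of 0.159 in pairs with the same replicate number and -0.0544 in other pairs.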

Other observations

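The tests of single genes and lists here were fixed before the data were examined, and the granule genes outside the correlated probes and the correlations between ages were chosen after.

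Genes of oxidative phosphorylation were lower at week 7 than at week 1 for 29 of 40 measured members, with a median of -0.10 (camera, adjusted p = 0.0519, which did not pass). The list passed in 20 of 58 settings, among them fry (adjusted p = 0.00325), and had an adjusted p of 0.316 with an estimated correlation. Besides SDHD, which rose, 5 members passed, all downward, namely ATP5J2 (-0.37), NDUFB9 (-0.36), ATP5B, the catalytic beta subunit of ATP synthase (-0.29), ATP5PB (-0.28) and COX6C (-0.27). With a loess per grid block the adjusted p was 0.0554 for ATP5J2, 0.411 for NDUFB9 and 0.351 for ATP5B, and with the header day as a block none passed. Of 29 genes of protein folding and stress in the endoplasmic reticulum, with a median of -0.0185, 3 passed upward, CRELD2 (0.44), HERPUD1 (0.43) and SEC61B (0.22). The 2 that passed downward were ERO1A (-0.41) and HSPA5 (-0.31, adjusted p = 0.0475). With a loess per grid block CRELD2 (adjusted p = 0.0622), ERO1A (0.115) and HSPA5 (0.111) did not pass, and their calls were lost in 23, 12 and 35 settings. HSPA5 was saturated on 11 of 32 arrays.

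Outside the probes that varied together, 9 granule genes had a median change of 0.21 from week 1 to week 7, and 4 of them passed upward. The list of genes of the female-specific W chromosome had 2 measured members, too few to be tested. Between the lines HINTW differed by 0.10 (adjusted p = 0.604) and ATP5F1AW by -0.20 (adjusted p = 0.374). Line differences correlated across probes between pairs of ages at 0.14 to 0.369, where probes are not independent replicates.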
